A study of Escherichia coli str. K-12 substr. MG1655 with 6 samples.

How the data were processed

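Escherichia coli K-12 MG1655, a standard laboratory strain, was cultured in M9 minimal medium or in M9 with added amino acids. M9 is a defined salts medium, so cells in it without amino acids must make their own. Cells were collected at an optical density of 0.4, and each group holds 3 libraries from cultures of separate days, per the labels' protocols and the design text of the series. Total RNA was purified on columns, ribosomal RNA was depleted, and stranded paired-end libraries were sequenced on an Illumina instrument, per the labels' protocols. Samples were grouped by the medium in their titles.

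The deposited files hold 1 gene table per library in the format of RSEM, per the file headers. RSEM 1.2.19 and Bowtie2 2.2.3 are named without their roles, per the submitters' processing notes. The genome build, the annotation, the strand setting and any filter of reads are not given in the sources used here. Each table has 4623 gene IDs with the length of each gene in nucleotides. The expected counts are the authors' estimates of the fragments from each gene, per the file headers, and their totals differ between libraries. Decimals beyond a tolerance of 0.005 stood in the counts of 156 genes, as RSEM gives where reads are shared between genes. The TPM values, which correct for gene length and have the same sum in every library, were also deposited by the authors, per the file headers. The FPKM values deposited by the authors were not used in any test.

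The gene IDs are codes, and the files do not pair them with gene symbols. In a reference table of RefSeq genes (assembly ASM584v2), 8 of the 4623 IDs matched. Of these, 6 stood among the synonyms of a gene, and RUVA and RUVB spell a symbol in capitals. Lists of gene symbols for the pathways of interest and for ribosomal RNA were fixed before the data were examined, as were the tests and the first set of alternatives below. With this reference table the lists could not be laid over the coded IDs, and no other table of names was used. The planned list tests and the share of transcripts per list were therefore not run, and results are given for gene IDs and for classes of genes. The planned exclusion of ribosomal RNA was not applied for the same reason. Of 27 IDs with the length of a reference ribosomal RNA gene, 22 had 0 counts in every library, among them all 7 with the length of the longest kind. No coordinates are given, because the build of the files is not stated.

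Total expected counts per library ran from 826253 to 22677224. The shallowest library, replicate 1 of M9 plus amino acids, had a median count of 30 per tested gene, against 766 in the deepest. Chi-square per degree of freedom between replicates of a group was at least 20.6, so that no pair agreed within sampling noise. Limits set from counts of 0 cover counting error only.

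Expected counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on all 6 libraries with the medium as the only term. Genes were filtered with filterByExpr, which left 4102, and libraries were scaled by TMM (trimmed mean of M-values). P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are M9 plus amino acids over M9 minimal. The standard error of a log2 change was taken as its size divided by the square root of its F statistic. CPM are counts scaled by the TMM-adjusted library total. Shares of the transcript pool are percentages of summed TPM. The part of the pool in other genes is the sum of absolute differences in share over all genes, divided by 2. Single measures were compared with exact two-sided permutation tests, in which 3 against 3 libraries cannot give a p below 0.1.

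The rule for named genes took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups. Because the IDs are codes, only the first 2 of each direction are given by ID, together with the IDs that matched a symbol, which were chosen after the data were seen. Classes by length, by level and by shared reads were also set after the data were seen. The test was tried on simulated counts with the means, totals and dispersions of these libraries. Among 4080 simulated genes it recovered 51.5% of 99 genes changed 2-fold and 100% of 99 genes changed 4-fold, and 3.23% of its calls were false. The simulated share of changed genes was below the 24.3% of tested genes called in the data. Genes were drawn independently, without differences shared across a library. These rates may therefore not carry over to the real libraries.

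The alternatives fixed at that point were DESeq2 size factors, library totals alone, no low-count filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), the replicate number as a block, genes under 200 nt left out, an adjusted p under 0.01, and each library left out in turn. Chosen after seeing the data were leaving out the replicate 1 libraries of both groups, thinning all libraries to the shallowest, limma voom with library weights, and summing genes with identical counts to 1.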

Results

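The transcriptome of Escherichia coli K-12 MG1655 was measured by RNA sequencing in M9 minimal medium and in M9 with added amino acids, with 3 cultures in each. The comparison asks which transcripts differ between cells without and with amino acids in the medium. The libraries of M9 minimal held 4857238, 9870151 and 11915719 expected counts in replicates 1, 2 and 3. Those of M9 plus amino acids held 826253, 20741539 and 22677224. Of 4623 gene IDs, 253 had no count in any library and 4102 passed the low-count filter. The files do not pair the IDs with gene names.

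With amino acids, 421 genes rose and 577 fell, together 998 or 24.3% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the called genes, 615 had a fitted change of at least 2-fold, of which 236 were higher and 379 lower. The test was against no change and not against a 2-fold change. The median called rise was 1.10 on the log2 scale and the median called fall was -1.24. Falls also outnumbered rises among called changes of at least 4-fold, with 149 against 90. Among changes of at least 8-fold there were 48 rises and 42 falls, and among those of at least 16-fold 22 of each. The groups did not overlap in 965 of the called genes (96.7%), and in 40.8% of all tested genes, where chance gives 10%. On log2(TPM + 1) with limma, 235 genes were called higher and 550 lower, so that 29.9% of calls were rises against 42.2% in the count test. In that alternative, which changed the test, the values and the scaling together, the log2 change of the median gene was shifted by -0.13 relative to the count test. Without replicate 2 of M9 plus amino acids 615 genes were called (254 higher, 361 lower), without its replicate 3 there were 644 (285 higher, 359 lower), and without replicate 2 of M9 minimal 270 were called higher.

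**Figure D1:**
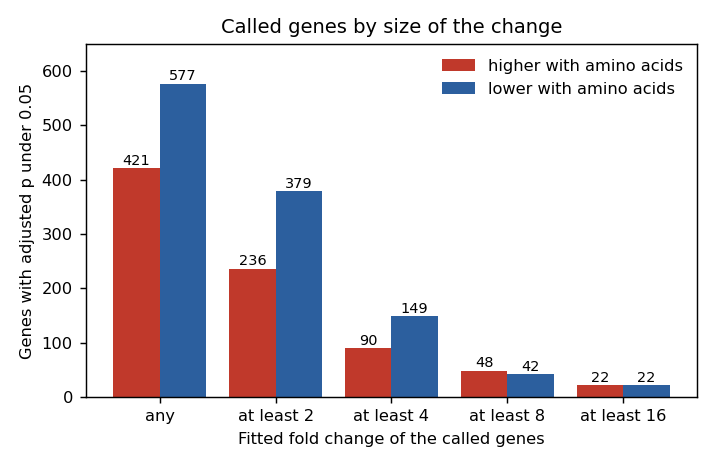
Number of genes called at an adjusted p under 0.05 (vertical axis) by the smallest fitted fold change counted (horizontal axis), with genes higher with amino acids in red and lower in blue. Falls outnumber rises over all called genes (577 against 421), at 2-fold or more (379 against 236) and at 4-fold or more (149 against 90), rises are more at 8-fold or more (48 against 42), and the counts are equal at 16-fold or more (22 each).

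The largest fitted rise in the named set was that of G6836 (657 nt), whose rounded count was 0 in all 3 libraries of M9 minimal. With amino acids it reached 32.1, 27.7 and 3.02 CPM in replicates 1, 2 and 3. The fitted rise passed the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00534). Against a limit of 3 counts over the M9 minimal group, its mean level with amino acids was at least 183-fold higher. This limit covers counting error in M9 minimal and not the spread between the libraries with amino acids. Without replicate 2 or 3 of M9 minimal the limit allowed 116-fold and 105-fold. Part of its counts were fractional, so its level is uncertain where reads were shared with other genes. EG12268 (1209 nt) rose from 3.76 ± 1.66 to 386 ± 285 TPM (SD, n = 3 per group). Its log2 change was 6.90 with a standard error of 0.81 (adjusted p = 0.000242, edgeR quasi-likelihood, Benjamini-Hochberg). Its replicates with amino acids were uneven, at 114, 1112 and 982 CPM, and each lay above the highest library of M9 minimal, at 8.47 CPM. Its log2 change was 5.85 on log2(TPM + 1) with limma and 7.64 without the replicate 1 libraries of both groups. The 10 named rises averaged at most 33.2 TPM in M9 minimal and between 23.5 and 955 TPM with amino acids.

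The largest falls in the named set were those of G6321 (333 nt) and G6320 (1374 nt). G6321 fell from 420 ± 32.8 to 2.74 ± 2.44 TPM (SD, n = 3 per group), a log2 change of -6.58 with a standard error of 0.33 (adjusted p = 4.6e-06, edgeR quasi-likelihood, Benjamini-Hochberg). In replicate 1 of M9 plus amino acids, the shallowest library, it had 0 counts. G6320 fell from 129 ± 21.5 to 1.30 ± 1.13 TPM, a log2 change of -6.24 with a standard error of 0.50 (adjusted p = 3.76e-05, edgeR quasi-likelihood, Benjamini-Hochberg). Without replicate 2 of M9 plus amino acids its log2 change was -7.30. With all libraries thinned to the shallowest, the log2 changes of G6321 and G6320 were -7.64 and -7.12. The 10 named falls averaged 99.0 to 3417 TPM in M9 minimal and 1.30 to 108 TPM with amino acids, with log2 changes from -6.58 to -4.58.

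**Figure D2:**
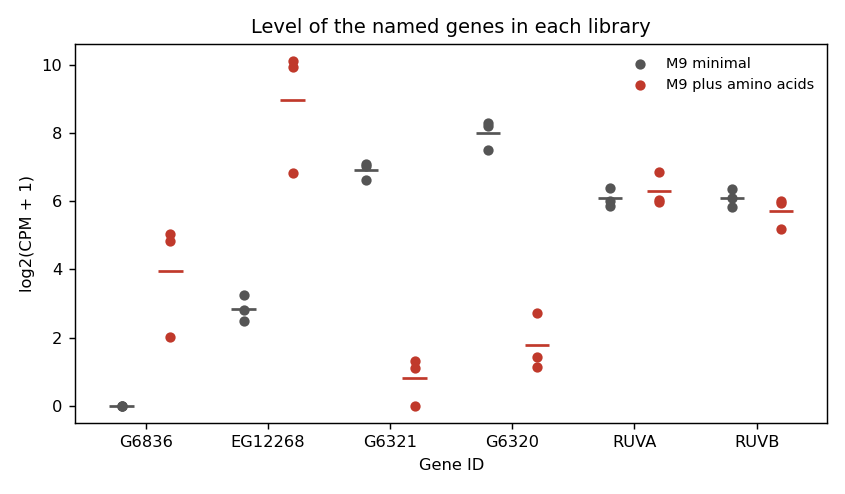
Level of the 6 genes named by ID as log2(CPM + 1) on the vertical axis, with each point 1 library (grey for M9 minimal, red for M9 plus amino acids) and each bar the mean of 3. G6836 and EG12268 lie higher and G6321 and G6320 lower with amino acids in every library, while the groups overlap for RUVA and RUVB.

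RUVA and RUVB matched ruvA and ruvB, which encode the subunits of the Holliday junction branch migration complex of DNA recombination and repair. Their lengths, 612 and 1011 nt, equalled those of the reference genes. RUVA averaged 92.4 ± 29.7 TPM in M9 minimal and 98.9 ± 37.8 TPM with amino acids (SD, n = 3 per group). Its log2 change of 0.20, with a standard error of 0.27, did not pass the test (adjusted p = 0.624, edgeR quasi-likelihood, Benjamini-Hochberg) and was -0.071 without replicate 1 of M9 plus amino acids. RUVB averaged 48.2 ± 6.08 and 34.5 ± 9.61 TPM. Its log2 change of -0.31, with a standard error of 0.24, did not pass either (adjusted p = 0.384, edgeR quasi-likelihood, Benjamini-Hochberg). The other 6 matched IDs stood among the synonyms of ylbE, mntS, azuR and the pseudogene ygaQ. Their lengths differed from those of the reference genes, though for azuR only as 160 against 159 nt, and none passed the low-count filter. The IDs matched to mntS and azuR had no count in any library.

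Abundant transcripts changed in both directions. Of the 100 genes with the highest mean CPM over the 6 libraries, 15 rose and 11 fell, with a median log2 change of 0.33. Of the other 4002 tested genes, 406 rose and 566 fell. CPM do not correct for gene length. Of 187 genes with a mean of 1000 TPM or more in M9 minimal, 20 rose and 35 fell. Of 165 genes at that level with amino acids, 32 rose and 3 fell. A set chosen on 1 medium favours genes that are higher in it. From 100 TPM or more in M9 minimal to under 10 TPM with amino acids went 8 genes, and 4 genes went from under 10 TPM to 100 TPM or more. Each of these was called.

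The genes called lower held 16.6% ± 1.86 of the transcript pool in M9 minimal and 5.21% ± 0.0955 with amino acids (share of summed TPM, SD, n = 3 per group). The genes called higher held 10.2% ± 0.387 and 21.3% ± 1.39. These genes were chosen on the same libraries, so the shares describe the size of the change and do not test it. The 20 called genes that gained most went from 6.55% ± 0.769 to 13.6% ± 1.45, and the 20 that lost most from 6.12% ± 0.596 to 1.60% ± 0.0930. The 100 most abundant genes of each library held 48.4% ± 5.29 of the pool in M9 minimal and 55.3% ± 0.876 with amino acids (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The difference of 6.86 percentage points was 3.92 without replicate 1 of M9 minimal and 3.46 in shares of expected counts. The 10 most abundant genes held 13.8% ± 1.90 and 14.0% ± 0.0463 (exact permutation p = 0.7, two-sided).

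Between the group means, 19.3% of the TPM pool lay in other genes. The highest value among the 9 other splits of the libraries into 3 and 3 was 11.9% (exact permutation p = 0.1, the smallest possible). Replicate 1 of each group stood apart from the other replicates of its medium. In M9 minimal it differed from replicates 2 and 3 by 17.3% and 16.1% of the pool, where these differed from each other by 8.42%. With amino acids it differed from them by 15.0% and 14.5%, where they differed by 5.27%. With the replicate 1 libraries of both groups left out, 1667 genes were called, 797 of them higher and 870 lower. At 2-fold or more, 296 were then higher and 416 lower.

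**Figure D3:**
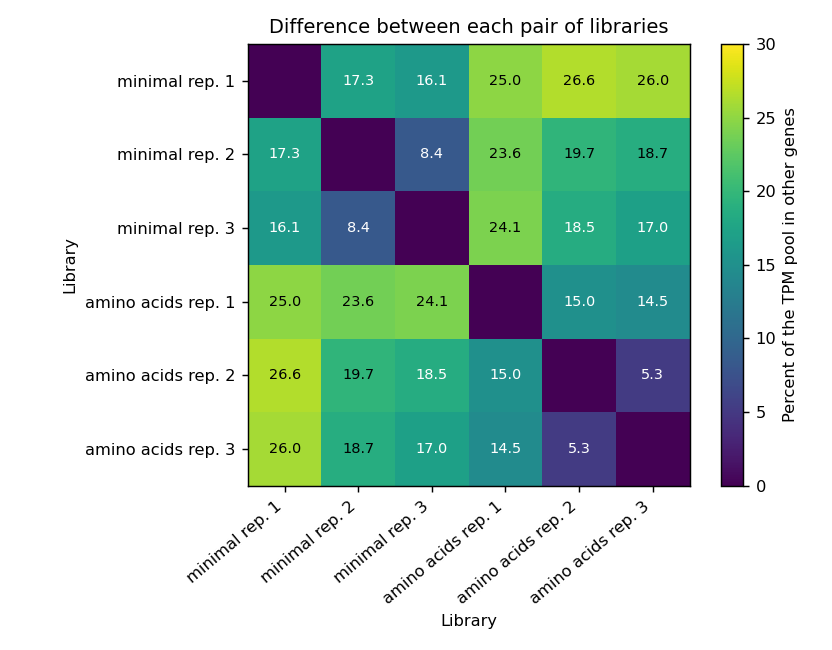
Percent of the TPM pool that lies in other genes between each pair of the 6 libraries, with libraries on both axes and the value in each cell. Replicates 2 and 3 are the closest pair in each medium (8.4% and 5.3%). The other pairs within a medium range from 14.5% to 17.3%. Pairs across media range from 17.0% to 26.6%, so these ranges overlap.

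Of the 821 tested genes with the lowest mean CPM, at most 6.28, 4.26% were called higher and 5.12% lower. Changes are harder to call at low counts, so these shares do not show that such genes changed less. Of the 821 with the highest mean CPM, 13.0% were called higher and 16.9% lower, and in the classes between them 10.9% to 12.2% were higher and 13.0% to 18.0% lower. By length, rises and falls numbered 6 and 10 among 61 genes under 200 nt, 68 and 60 among 547 genes of 201 to 399 nt, and 127 and 148 among 1250 genes of 402 to 798 nt. They numbered 169 and 291 among 1754 genes of 801 to 1599 nt, and 51 and 68 among 490 genes of 1602 nt or more. The median log2 changes of these classes were 0.0023, 0.097, 0.049, -0.062 and 0.0036, in no order with length.

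**Figure D4:**
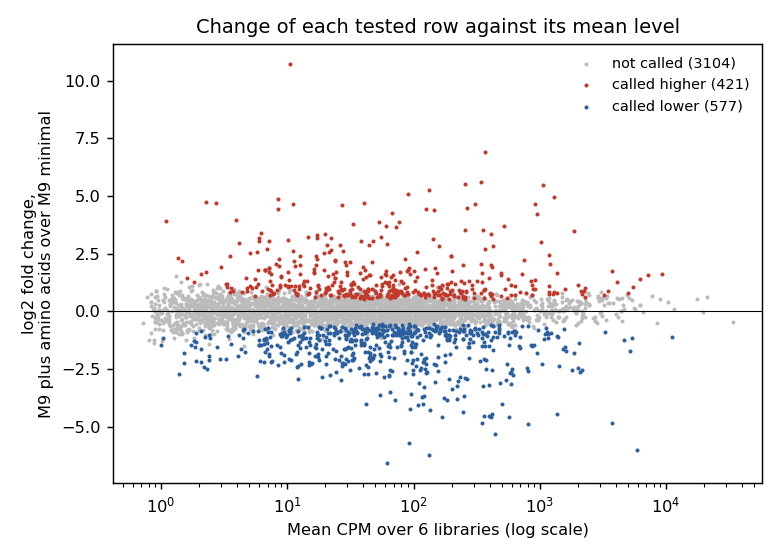
Fitted log2 fold change with amino acids (vertical axis) against mean CPM over the 6 libraries (horizontal axis, log scale), with each point 1 of 4102 tested genes. Red points are the 421 genes called higher, blue points the 577 called lower and grey points the 3104 not called.

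A fractional count appeared in 156 genes, of which 132 were tested, 10 were called higher and 7 lower. With a mean expected count of at least 1, 62 genes had counts and length identical to another gene and formed 15 sets of up to 9, so that each set is 1 measurement. Of these genes 5 were called, all higher and from 2 sets.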

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

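The alternatives that leave out both replicate 1 libraries, thin the libraries, weight them or sum identical genes were chosen after the results were seen, and the others before. With edgeR or DESeq2 on all libraries at their full depth, calls ranged from 874 to 1298, and none of the 998 called genes changed sign in any alternative that tested it. At an adjusted p under 0.01, 584 genes were called (237 higher, 347 lower). With limma on log2(TPM + 1), 235 were called higher, and 735 of the 998 kept their call. Leaving out 1 library at a time gave 615 to 1151 calls, with 254 to 506 higher and 359 to 645 lower. Whichever library was left out, 546 genes kept their call (221 higher, 325 lower), 496 of them with a fitted change of at least 2-fold on all libraries. Calls with a fitted change of at least 2-fold ranged from 486 to 712. Leaving out the replicate 1 libraries of both groups gave 1667 calls (797 higher, 870 lower), and limma voom with library weights gave 1753 (826 higher, 927 lower), which held all 998. Thinning every library to 826256 rounded counts left 2937 genes tested and 672 called, with G6836 not tested. G6836, EG12268, G6321 and G6320 kept their calls at 0.05 in every other alternative, with adjusted p up to 0.0223 for G6836. RUVA ranged from -0.071 (without replicate 1 of M9 plus amino acids) to 0.37 when 1 library was left out, never past the threshold. The cause was not tested for these shifts. The part of the pool in other genes was 18.8% to 20.7%. With the replicate number as a block, 1298 genes were called (593 higher, 705 lower), 991 of the 998 among them. The labels do not say that a number marks a day shared across media, deviations from the group means correlated by 0.23, 0.018 and 0.31 for numbers 1, 2 and 3, and 4 of the 6 libraries correlated best with their own number. As number 2 stayed under 0.1, samples were not paired. Deviations sum to 0 within a medium, so that value leaves pairing open. In the blocked fit 684 genes differed between numbers at an unadjusted p under 0.05 (205 by chance). At an adjusted p under 0.05, 4 did (edgeR quasi-likelihood, Benjamini-Hochberg). At these depths 51.5% of simulated 2-fold changes were recovered, with a smaller share of genes changed than was called here. The alternatives on gene lists and on ribosomal RNA were not run.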

Other observations

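The tests of other splits of the libraries, of gene length and level, of a shared day and of normalization were chosen after their results were seen. For the 998 calls, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many. Every other split gave 0 calls with the edgeR quasi-likelihood test. At an unadjusted p under 0.05 the other splits gave 3 to 334 genes, against 1503 in the real split. With 10 splits the share cannot fall under 0.1. Each other split also mixes the media within its groups, so a difference between media adds to the spread within groups and can lower the calls. The 0 calls are therefore no baseline for what chance gives.

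Genes with consecutive ID numbers changed alike. Over 3435 pairs with the same prefix and consecutive numbers, without genes of fractional counts, log2 changes correlated across genes with r = 0.355 and Spearman rho = 0.29, where the highest of 100000 shuffled orders gave r = 0.0758 (two-sided permutation p = 1e-05 for r, the smallest they can give). Where both genes of a pair were called, 270 of 346 pairs (78.0%) moved in the same direction. With 421 calls higher and 577 lower, unrelated called genes would also often share a direction, and that share was not computed. Genes are not independent replicates. Whether ID numbers follow groups of related genes stays open, since only 2 pairs of consecutive numbers had both IDs matched to the reference table. The IDs of these pairs (G7391, G7392 and G7393) all stood among the synonyms of the pseudogene ygaQ, and none passed the low-count filter.

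Replicate 1 of M9 plus amino acids lay apart from the other 2 of its medium, with 12.6% and 11.3% of the counts in other genes. Low depth as the whole cause is argued against, since replicates 2 and 3 thinned to its total differed by 6.56% ± 0.0607 (SD over 20 draws), against 5.79% at full depth. Gene length and level took 17.9% of the variance of its log2 differences. The level was the mean of its medium, which included replicate 1 itself, so some of this trend may be built in. The value therefore cannot tell whether a trend of that kind is part of the pattern. Its deviations correlated by 0.23 with those of replicate 1 of M9 minimal. The libraries of numbers 2 and 3 correlated by 0.018 and 0.31. Deviations sum to 0 within a medium, so the values of the replicate numbers are tied and none is a separate check. These correlations cannot tell a shared day apart from other differences of these libraries. No biological explanation was tested.

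More genes fell than rose, 577 against 421. At 8-fold or more there were 48 rises and 42 falls and at 16-fold or more 22 of each, differences that were not tested. Rises were 42.2% of calls in the count test, 43.2% with DESeq2 size factors and 40.04% with library totals alone, scalings that moved the median gene little, but 29.9% with log2(TPM + 1). They were 47.8% without the replicate 1 libraries of both groups and 47.1% with limma voom and library weights. The log2(TPM + 1) alternative changed the test, the values and the scaling together, and these were not separated, so normalization stays open, as does a difference between the media, which was not tested.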
